A study of Homo sapiens with 16 samples.

How the data were processed

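RNA from cultured neuroblastoma cells was hybridised to 16 expression arrays of the human U133 Plus 2.0 kind, 1 array per sample. All samples are SK-N-AS cells, an established human neuroblastoma line, or sublines of it, grown in high-glucose medium with serum, per the labels' protocols. The labels call 12 samples metastatic models and 4 samples primary models, and these are the groups compared. Titles also carry a number after the letter C, a number after the letter M and a suffix (Brain, FT, AG, jaw or TR). The labels do not explain these parts, so they are used only as they stand. The labels do not say that arrays of a group came from separate animals or separate cultures, so p-values measure only the spread between these samples, which may be technical.

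The authors deposited 1 table of log2 expression values with 54675 probe sets and 16 sample columns. The deposited values ran from 1.99 to 14.87, and the medians of the arrays lay between 6.36 and 6.44. After sorting, no array value lay further than 0.0933 from the mean of the arrays at the same rank, so the arrays share nearly 1 distribution. R 3.2.0 was used, per the submitters' processing notes. The background correction and the normalization method are not given in the sources used here. Array intensity has no count behind it, so the number of arrays limits the precision.

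Probe sets were paired with gene symbols through the platform annotation: 41097 had 1 symbol, 1801 had several and 11777 were not in that annotation. Probe sets with several symbols or none were left out. The 41091 probe sets used name 19775 genes, of which 10523 have more than 1 probe set, and the probe set with the highest mean over all arrays stood for its gene. A gene was tested where its value lay above the median of all probe sets of an array in at least 4 arrays, which left 12859 genes. Genes were put in chromosome order with a gene table of the assembly GRCh38.p14, used only for names, chromosomes and neighbours, because the coordinates of the array design were not used here.

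Differences were fitted on the log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Metastatic models were compared with primary models over all 16 arrays. A fit with 4 groups (primary, metastatic with the suffix Brain, metastatic with FT, other metastatic) gave Brain against FT, Brain against primary and FT against primary with 1 shared estimate of the spread. Before the data were examined, 30 gene lists were fixed with 551 distinct genes, and all 601 entries matched a current symbol, 4 of them through an older one. Lists with at least 5 tested genes were tested with camera in limma, two-sided, at a preset correlation of 0.01 and again with the correlation estimated per list. Whether metastatic arrays with the same C number resemble each other was tested with 100000 shuffles of that number.

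The rule for named genes was also fixed before the data were examined. For metastatic against primary it takes the 10 genes each way past the threshold with the largest difference, and where fewer pass, those with the smallest p. For Brain against FT it takes 6 each way, for each list described up to 4 members with the smallest p, and whatever their values CADM1, SPHK1, YAP1, MYCN, MYC and CXCR4. A further gene fixed in that rule and a further control check of array quality are not reported here.

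The fits for metastatic against primary and for Brain against FT, and the list test, were tested on simulated data first. Array weights and the shuffles of the C number were not simulated. Over 12859 genes simulated for metastatic against primary, the fit recovered 58% of 50 genes changed by 0.5 on the log2 scale, 88% at 1, 96% at 2 and 98% at 3, with 11 false calls. For Brain against FT, over as many simulated genes, it recovered 40% at 0.5, 84% at 1, 98% at 2 and 100% at 3, with 10 false calls. In 10 simulations with no change, 2 genes were called for metastatic against primary and 0 for Brain against FT. The list test called 0 lists there in either comparison. Among 100 splits of the real arrays, lists were called in 84 other than the real one for metastatic against primary. For Brain against FT it was 91. The simulations did not reproduce these calls, so they lack structure of the real arrays. The recovery rates hold for the simulated data and may be too high for the real arrays.

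Alternatives were other filters, another normalization, the mean of all probe sets, another variance model, array weights, the C number as a random block, a 2-fold minimum, leaving out each array in turn and subsets of arrays. Array weights let limma give less influence to arrays that lie far from the fitted mean of their group. In the random regroupings with array weights, the weight estimate stopped short of its tolerance in 1 fit. Counts over splits of the samples used 100 splits, the real one included, or all 35 where there were no more. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.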

Results

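Expression was measured in 12 metastatic and 4 primary models of neuroblastoma, a childhood tumour of the sympathetic nervous system, on 16 arrays. The cells were SK-N-AS or sublines grown in culture. Among the metastatic models, 6 titles end in Brain, 4 in FT, 1 in AG and 1 in jaw. Among the primary models, 2 titles end in AG, 1 in jaw and 1 in TR. Pairwise correlations over the tested genes ran from 0.871 to 0.992 over 120 pairs. For 6 arrays, 3 metastatic and 3 primary, the most correlated array carried the other label. The first principal component held 36.5% of the variance and ran from -27.4 in the metastatic array C21M3Brain to 60.4 in the metastatic array C21M2Brain. Of the primary arrays, C1M4AG lay at 42.8, C7M2AG at 28.0 and SKNASTR at 21.4, while C3M1jaw lay at -21.3 among most metastatic arrays. The metastatic array C2M4AG lay at 37.0, among the primary arrays.

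Control probe sets set 1 array apart. In the metastatic array C7M1jaw (metastatic replicate 11) the 3' probe set of GAPDH lay 5.78 log2 units above the 5' probe set, and that of ACTB lay 7.37 above. Across the other arrays the GAPDH difference ran from -0.10 to 0.04 and the ACTB difference from 0.09 to 0.57, with 0.57 in C21M2Brain (metastatic replicate 5). The 5' probe set of the 18S ribosomal RNA control read 8.3 in C7M1jaw and 11.2 in C21M2Brain, against 13.6 to 14.1 in the other 14 arrays.

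**Figure D1:**
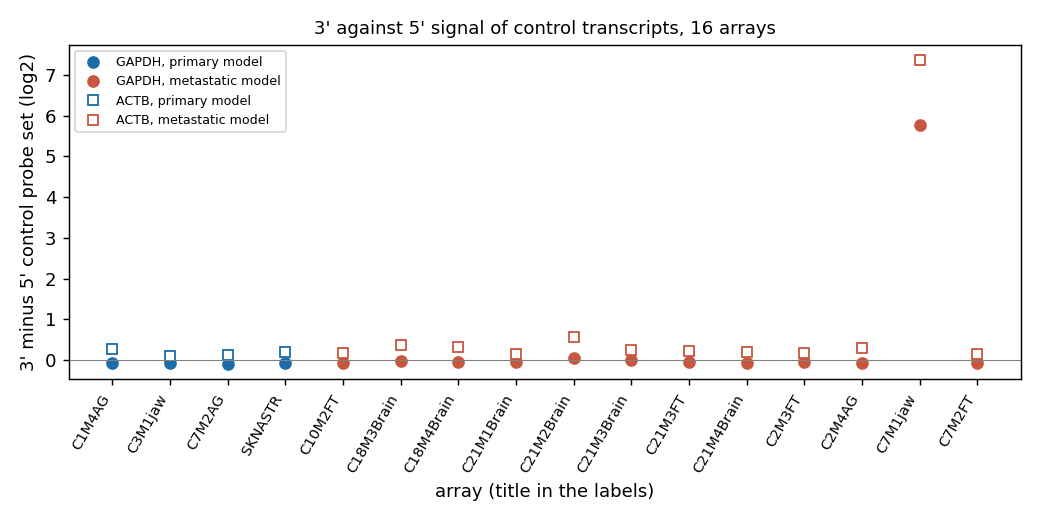
The 3' minus 5' difference of the control probe sets (y axis, log2) for each of 16 arrays (x axis), with filled circles for GAPDH, open squares for ACTB, blue for primary and red for metastatic models. The array C7M1jaw lies at 5.78 and 7.37, and all other arrays lie at or below 0.57.

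The series asks which genes go with metastasis in these models, and the first comparison sets metastatic against primary models. The 10 genes with the smallest p in the upward direction included IGFBP2, which binds insulin-like growth factors, with a mean of 11.87 ± 0.78 (SD, n = 12) in metastatic and 9.78 ± 1.41 (SD, n = 4) in primary models, a difference of 2.09 (SE 0.51, 4.26-fold). HDAC9, a histone deacetylase, had 7.90 ± 1.00 and 5.98 ± 0.46, a difference of 1.92 (SE 0.49). Its primary arrays, at 5.48 to 6.41, lay near or below their medians, so its size is not measured on both sides. CD2AP, an adaptor between membrane proteins and actin, differed by 0.48 (SE 0.12), and the phospholipid scramblase ANO6 by 0.39 (SE 0.10). In the downward direction, the tight-junction protein CLDN4 had 6.35 ± 0.45 and 7.56 ± 0.87, a difference of -1.21 (SE 0.31). The lysophosphatidic acid receptor LPAR3 differed by -1.18 (SE 0.32), and CAVIN2, a coat protein of caveolae, by -1.12 (SE 0.29). The metastatic means of CLDN4 (6.35), CAVIN2 (6.16) and LPAR3 (6.63) lay near or below the array medians, so these sizes are not measured on both sides. Within C number 7, with no test, CAVIN2 differed by only -0.38. On leaving out each array, IGFBP2 ran from 1.70 to 2.77. With only the arrays of the suffix AG or jaw, 2 metastatic and 3 primary, IGFBP2 differed by 0.45, CLDN4 by -0.64 and LPAR3 by -0.50. With the mean of all probe sets, CD2AP differed by 0.27, ANO6 by 0.15 and CLDN4 by -0.62.

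None of these differences passed the test. Of 12859 genes, 0 passed in limma at an adjusted p of 0.05, and the smallest adjusted p was 0.762. An unadjusted p under 0.05 was reached by 833 genes, or 6.48%, with 508 higher and 325 lower in metastatic models. In 13 genes the groups did not overlap, where chance gives 14.1 (0.11% of genes). With array weights 726 genes passed, 423 higher and 303 lower. Without weights, leaving out any 1 array gave 0.

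The other upward genes named by the rule were MYL12A (0.30, SE 0.06), a light chain of myosin, USP38 (0.41), SLC25A4 (0.37), MTARC2 (0.65) and ENPP4 (0.78). MYL12B (0.31) has a near-identical sequence to MYL12A, so the 2 values are uncertain as separate measurements. The other downward genes were INAFM1 (-0.56), YBEY (-0.44), PLEKHG4B (-1.24), PTPRN (-0.88), IL13RA2 (-0.53), MEIS3 (-0.41) and SLC27A3 (-1.13). Of these, PTPRN gave -0.20, IL13RA2 -0.19 and MEIS3 -0.25 among the AG and jaw arrays alone. The metastatic means of PLEKHG4B (6.445) and PTPRN (6.643) lay near the array medians, so their sizes are not measured on both sides. All 12 metastatic arrays lay beyond the primary mean for 18 of these 20 genes, and 11 did so for IL13RA2 and LPAR3. The genes were chosen for a small p in the same arrays, so this is no independent support. The 4 primary arrays were not alike: IGFBP2 read 11.82 in C3M1jaw and 9.45, 9.21 and 8.62 in C1M4AG, C7M2AG and SKNASTR, while CLDN4 read 6.27 in C3M1jaw and 8.10, 7.78 and 8.10 in the others.

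**Figure D2:**
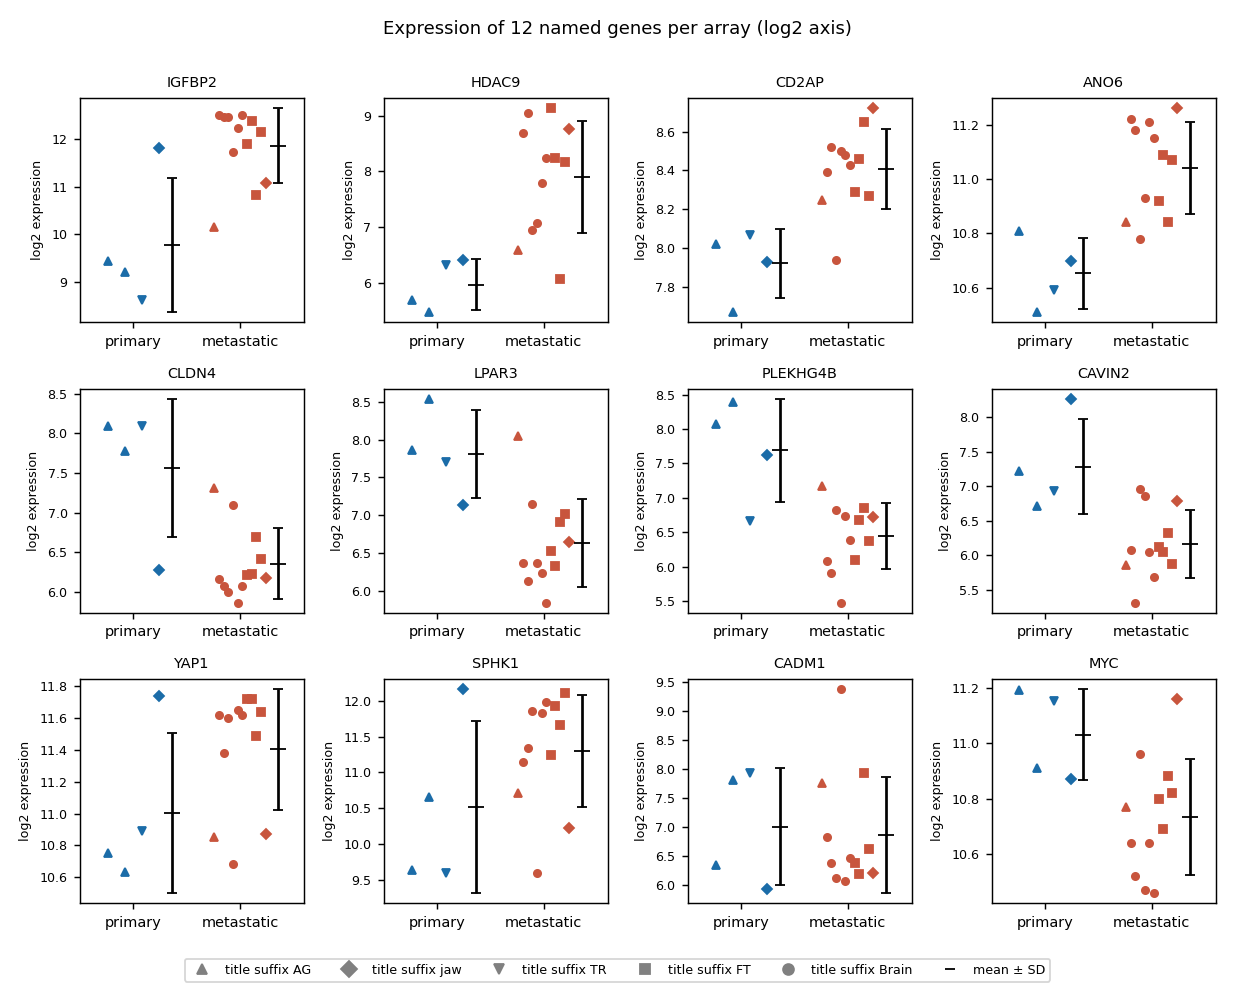
Expression (y axis, log2) of 12 named genes in the 4 primary (blue) and 12 metastatic (red) arrays, with a marker shape per title suffix and the mean ± SD in black beside each group. IGFBP2 has means of 9.78 and 11.87 and CLDN4 of 7.56 and 6.35, and the primary jaw array lies with the metastatic arrays in both.

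Genes named whatever their values gave small or variable differences. The transcriptional coactivator YAP1 had 11.40 ± 0.38 (SD, n = 12) in metastatic models and differed by 0.40 from primary models (SE 0.22, 95% interval -0.07 to 0.87), with 9 of 12 metastatic arrays above the primary mean. SPHK1, which makes sphingosine-1-phosphate, differed by 0.79 (95% interval -0.22 to 1.80), and the adhesion molecule CADM1 by -0.15 (95% interval -1.29 to 0.99). MYC, a growth-promoting transcription factor, had 10.73 ± 0.21 and 11.03 ± 0.17, a difference of -0.29 (p = 0.0213 and adjusted p = 0.762 in limma). Its relative MYCN differed by 0.11 (95% interval -0.08 to 0.31) at a level near the array median. The chemokine receptor CXCR4 did not enter the test, with 5.59 ± 0.33 and 6.24 ± 1.31 and only 2 arrays above their median. On leaving out each array, SPHK1 ran from 0.48 to 1.34 and YAP1 from 0.28 to 0.65. With only the arrays of the suffix AG or jaw, YAP1 gave -0.18 and SPHK1 -0.35, and CADM1 turned to 0.12 without C7M2AG and 0.16 without SKNASTR.

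Of the 26 lists tested, 2 passed in camera with the preset correlation. YAP and TAZ with their targets, which respond to cell shape and tension, had 23 of 26 members higher in metastatic models and a mean difference of 0.42 (adjusted p = 0.00167, and adjusted p = 0.835 with an estimated correlation). GADD45A (0.37, SE 0.11), AMOTL1 (0.63, SE 0.29) and DLC1 (0.74, SE 0.39) had higher means and TEAD2 (-0.34, SE 0.13) a lower one. DLC1 gave 0.30 without C7M2AG and 1.23 without C3M1jaw. With the AG suffix as a covariate, a setting added after the data were seen, the list mean was 0.18 and the call was lost (adjusted p = 0.151). AMOTL1 then gave 0.22 and DLC1 0.42. The suffix is on 2 of the 4 primary arrays and 1 of the 12 metastatic. The list of mesenchymal neural-crest-like identity, transcription factors and markers of the less neuronal neuroblastoma state, had 18 of 21 members higher and a mean difference of 0.20 (adjusted p = 0.0295, and adjusted p = 0.835 with an estimated correlation). RUNX2 differed by 0.47 (SE 0.16), SIX4 by 0.64 (SE 0.34), IFI16 by 0.32 (SE 0.18) and SOX9 by 0.31 (SE 0.19), with IFI16 at 0.11 and SOX9 at 0.18 without SKNASTR. The call of this list was lost with the AG covariate (mean 0.11, adjusted p = 0.193), and without C18M4Brain, C21M1Brain, C7M2AG or SKNASTR (mean 0.16 to 0.27 on leaving out each array). In both lists 0 members passed over all genes and 0 adjusted over the list alone. Per array, the YAP and TAZ mean was 0.30 in the primary array C3M1jaw, and -0.92 in C21M2Brain and -0.42 in C2M4AG, both metastatic. The highest of all 16 arrays in both lists was C7M1jaw, the array with unusual controls, at 0.53 and 0.40. Without it the list means were 0.38 (adjusted p = 0.00364) and 0.17 (adjusted p = 0.0421). With the C number as a fixed block, added after the data were seen, they were 0.93 and 0.53, from C7M1jaw and C7M2FT against C7M2AG alone. The spread between primary arrays is not measured there, so no p-value is given.

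Collagens and matrix proteins had 16 of 23 members higher (mean 0.27, adjusted p = 0.0919 in limma). The list passed without C21M2Brain (adjusted p = 0.0344), C2M3FT (0.0186) or C2M4AG (0.0167), and its mean was 0.05 with the AG covariate. These calls used the preset correlation. With an estimated correlation in camera over all arrays, the adjusted p was 0.835 for this list and for the cell cycle and integrin lists below. THBS2, a matricellular thrombospondin, differed by 1.30 (SE 0.36) and LAMC1, COL5A1 and LAMB1 by 0.47, 0.45 and 0.34. Among the AG and jaw arrays alone THBS2 differed by 0.31, LAMC1 by 0.09 and COL5A1 by 0.19. LAMB1 ran from 0.21 to 0.38 on leaving out each array, and from 0.19 to 0.97 in the other alternatives. THBS2 was the 1 member that passed adjusted over the list alone (0.0498), with 0 over all genes. Cell cycle genes had 17 of 26 members lower (mean -0.14, adjusted p = 0.0919), with MCM2 at -0.56 (SE 0.24) and CCNE1 at -0.77 (SE 0.36). The mean was -0.07 without C18M3Brain and -0.06 with the AG covariate. The list passed without C1M4AG, C21M3FT, C21M4Brain, C2M3FT, C2M4AG, C7M2FT or SKNASTR, with means to -0.19 and adjusted p from 0.00771 to 0.0436. Integrins had 13 of 17 higher (mean 0.29, adjusted p = 0.258), led by ITGA9 at 2.43 (SE 0.92). The list passed without C21M2Brain (mean 0.37, adjusted p = 0.0495) and had a mean of 0.12 with the AG covariate, and ITGA9 differed by 0.59 among the AG and jaw arrays alone. ITGA9 lay below the median of the array in all 4 primary arrays, so its size is not measured on both sides. Adrenergic neuroblastoma identity had 9 of 16 higher, with a median of 0.11, a mean of -0.03 and a test direction upward (adjusted p = 0.917). ISL1 differed by 0.41 (SE 0.17), STMN2 by 1.12 (SE 0.58) and HAND1 by -0.88 (SE 0.51), the last with -0.30 without C7M2AG and -1.46 without C1M4AG. STMN2 gave 0.68 without C3M1jaw and 1.74 without C1M4AG, and ISL1 0.27 without C7M2AG. THBS2 also passed adjusted over the list alone among angiogenesis factors, as did IL13RA2 among chemokines, cytokines and receptors, again with 0 over all genes.

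Median, mean and test differed in sign in further lists that did not pass. The cell adhesion list had a median of -0.01, a mean of 0.15 and an upward test, and matrix proteases had -0.01, 0.10 and an upward test. Bone metastasis genes had -0.08, 0.01 and a downward test, housekeeping genes 0.01, -0.02 and a downward test, and the interferon list 0.04, 0.00 and a downward test. Markers of other cell types were few: 4 endothelial, 4 glial and brain, 2 Schwann and 0 adrenal cortex genes passed the brightness filter, so these lists were not tested. Hypoxia and glycolysis (mean 0.08), Wnt signalling (-0.07), neuronal differentiation (-0.14) and HLA class I (-0.06) did not pass either, with adjusted p from 0.389 to 0.999 in camera. Blood and immune markers had 5 of 6 members lower (mean -0.08, adjusted p = 0.283).

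**Figure D3:**
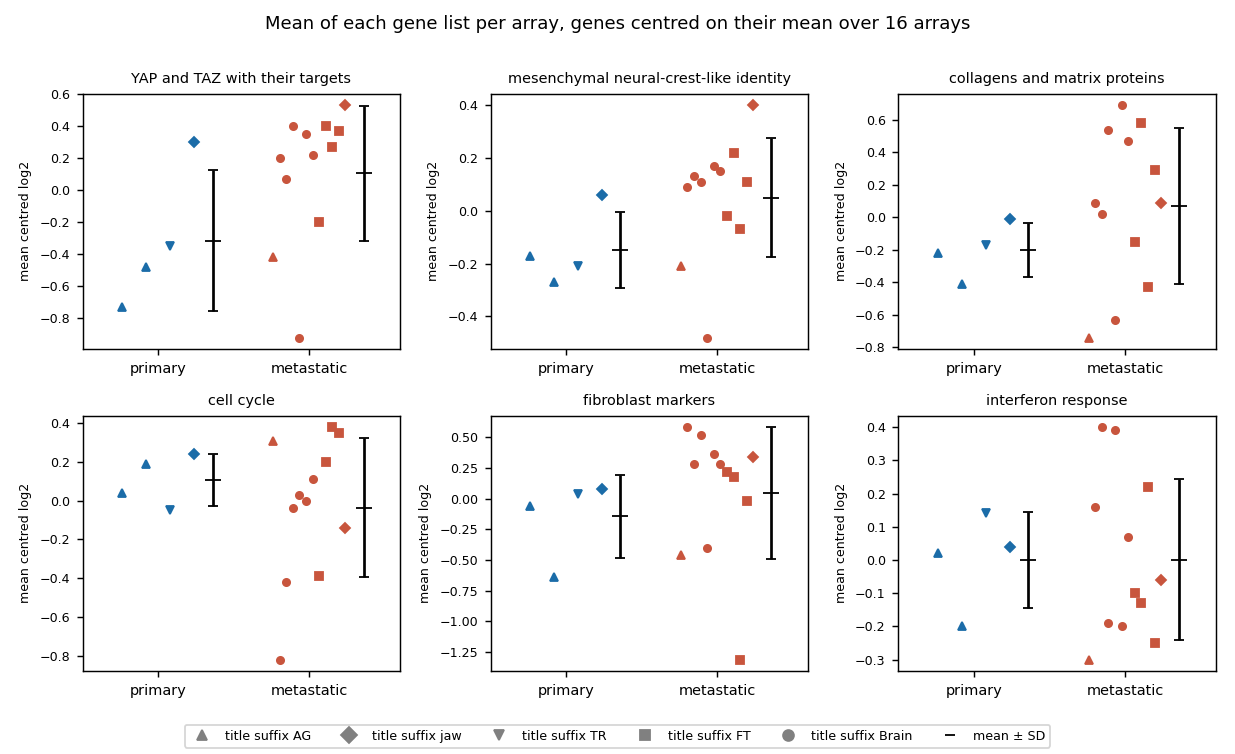
Mean of each of 6 gene lists per array (y axis, log2 with each gene centred on its mean over 16 arrays) in primary (blue) and metastatic (red) arrays, with a marker shape per title suffix and the mean ± SD in black. In the YAP and TAZ panel the primary arrays have a mean of -0.32 ± 0.44 and the metastatic arrays 0.11 ± 0.42, so the groups overlap.

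The next comparison sets the 6 metastatic arrays with the suffix Brain against the 4 with FT. The largest named differences upward in Brain were C1orf54 (1.33, SE 0.28), the soluble collectin COLEC11 (1.18, SE 0.26) and the complement factor CFB (0.99, SE 0.23), followed by MAPK10 (0.47), PSAP (0.46) and CNNM2 (0.41). Downward were MCAM, an adhesion molecule (-0.81, SE 0.19), ERVMER34-1 (-0.81, SE 0.20), SIX2 (-0.70), HMOX1, which degrades heme (-0.62), ETS2 (-0.51) and SLC5A3, the sodium and myo-inositol cotransporter (-0.47, SE 0.09). CFB had a mean of 5.77 in FT and ERVMER34-1 of 5.98 in Brain. Both means lay below the array medians, so the sizes for these genes are not measured on both sides. The 6 Brain arrays all lay below the FT range for SLC5A3, which its choice by a small p in the same arrays favours. None passed in limma: 0 of 12859 genes had an adjusted p under 0.05, the smallest was 0.942, and 560 had an unadjusted p under 0.05. MCAM passed adjusted over the list alone in the cell adhesion list and HMOX1 in the stress list. With the C number as a fixed block, added after the data were seen, C21M3FT was the only FT array that counted. C1orf54 then gave 1.23, COLEC11 0.645, CNNM2 0.21, PSAP 0.13 and SIX2 -0.32.

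In camera, 4 lists passed between Brain and FT, and 0 with an estimated correlation. Cell cycle genes had 26 of 26 members lower in Brain and a mean of -0.33 (adjusted p = 2.3e-08, and adjusted p = 0.715 with an estimated correlation). Per array, the list lay at -0.82 in C18M3Brain and -0.42 in C18M4Brain, at -0.04 to 0.11 in the 4 Brain arrays of C number 21, and at -0.39 in C10M2FT. Its mean difference was -0.20 without C18M3Brain and -0.50 without C10M2FT. Among them CDC20 differed by -0.60 (SE 0.27) and UBE2C by -0.46 (SE 0.22). MYC targets and ribosome biogenesis had 16 of 20 lower and a mean of -0.10 (adjusted p = 0.0375, and adjusted p = 0.824 with an estimated correlation), with ODC1 at -0.40 (SE 0.20). Leaving out each array gave list means of -0.14 to -0.06, and the call was lost without C18M3Brain, C18M4Brain, C21M1Brain, C2M3FT or C7M2FT, and with no filter on dim genes (adjusted p = 0.0551). ODC1 ran from -0.51 to -0.25 on leaving out each array and was -0.065 in another alternative. Fibroblast markers had 7 of 8 higher and a mean of 0.51 (adjusted p = 0.00278, and adjusted p = 0.715 with an estimated correlation), with LUM at 0.95 (SE 0.39) and DCN at 1.25 (SE 0.60). Much of this came from C2M3FT, where the list lay at -1.31: without that array the mean was 0.15 (adjusted p = 0.173), LUM 0.45 and DCN 0.43. The interferon list had 16 of 20 higher and a mean of 0.17 (adjusted p = 0.0133, and adjusted p = 0.715 with an estimated correlation), with IFIT2 at 0.67 (SE 0.27) and IFI35 at 0.32 (SE 0.11). Leaving out each array gave 0.11 to 0.27, and the call was lost without C10M2FT, C18M4Brain, C21M2Brain or C7M2FT. It was also lost with no filter on dim genes (mean 0.08, adjusted p = 0.107), without C7M1jaw and C21M2Brain (mean 0.11, adjusted p = 0.0933) and without the genes of 8 chromosomes that hold blocks of shifted genes (mean 0.10, adjusted p = 0.178). With the C number as a fixed block, added after the data were seen, Brain against FT rests on the 5 arrays of C number 21. The cell cycle mean was then -0.17, while the calls were lost for fibroblast markers (0.02), MYC targets (-0.01) and the interferon list (0.14). C21M3FT is the only FT array there, so the spread between FT arrays is not measured and no p-value is given. Of these 4 lists, 0 members passed over all genes and 0 adjusted over the list alone.

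In lists that did not pass, median, mean and test again differed in sign. The values were -0.03, 0.04 and upward for epithelial-mesenchymal transition, 0.08, -0.06 and upward for matrix proteases, and -0.04, -0.02 and upward for sphingosine-1-phosphate signalling. They were -0.04, 0.04 and downward for neuroblastoma oncogenes, 0.02, 0.01 and downward for Notch signalling, and 0.01, 0.01 and downward for blood and immune markers. Adrenergic identity had 13 of 16 members higher in Brain (mean 0.33, adjusted p = 0.0642). Per array the list lay at -0.83 in C2M3FT, and without that array the mean was 0.12 (adjusted p = 0.71). It passed with no filter on dim genes (adjusted p = 0.0477) and without C10M2FT, C21M1Brain, C21M3Brain, C21M3FT or C7M2FT (adjusted p from 0.0225 to 0.0369).

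Against the primary models, SLC5A3 fell by 0.79 in the Brain arrays (SE 0.09, adjusted p = 0.00541 in limma), with 11.57 ± 0.15 (n = 6) against 12.36 ± 0.15 (n = 4), and was lower in 6 of 6 arrays. It was the 1 gene of 12859 that passed, and 1120 genes had an unadjusted p under 0.05. The call was lost with the mean of all probe sets, where SLC5A3 differed by -0.94 (adjusted p = 0.285), and with a 2-fold minimum, which its difference does not reach. With the C number as a fixed block, added after the data were seen, SLC5A3 differed by -0.53. Brain and primary arrays share no C number, so that value is only indirect. It rests on C21M3FT and C7M2AG as single arrays of their group, so no p-value is given. Without C3M1jaw 6 genes passed. With array weights 1287 genes passed, and without C7M1jaw and C21M2Brain, left out after the data were seen, 290 did. FT against primary gave 0 genes in limma, with 693 at an unadjusted p under 0.05 and a smallest adjusted p of 0.814. There, 99 genes passed with array weights, 2 without C3M1jaw and 1 without C7M1jaw and C21M2Brain.

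For this test each gene was first centred on its mean over the metastatic arrays, so the correlations are not those of the raw values. Metastatic arrays that share a C number then had a mean correlation of 0.03 over 13 pairs, and those with different numbers -0.09 over 53 pairs. The difference of 0.12 had p = 0.174 in a two-sided permutation test, and was 0.30 without C number 21 (p = 0.0763).

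Expression also varied along the chromosomes within single arrays. Genes were put into 155 blocks of about 80 neighbours, and each block was set against its median over all arrays. In C10M2FT, 4 of 6 blocks of chromosome 10 had a median of -0.75 log2 units, and in C2M3FT all 5 blocks of chromosome 15 had -0.59. Chromosome 10 holds PSAP and CNNM2, named for Brain against FT. PSAP read 11.85 in C10M2FT and 12.12 to 12.33 in the other FT arrays. CNNM2 read 7.43 in C10M2FT and 7.34 to 7.59 in the others. On leaving out each array, PSAP ran from 0.37 to 0.53 and CNNM2 from 0.38 to 0.47. The end of chromosome 11 from JRKL to B3GAT1-DT, which holds YAP1 and CADM1, lay at -0.51 in C1M4AG, -0.58 in C7M2AG, -0.44 in SKNASTR, -0.48 in C2M4AG and -0.49 in C21M2Brain. These are 3 primary and 2 metastatic arrays. YAP1 read 10.75, 10.63, 10.89, 10.85 and 10.68 in these 5 arrays, 10.87 in C7M1jaw and at least 11.38 in the other 10. CADM1 did not read lower with the block, but many of its values lay near or below the array medians of 6.36 to 6.44. It read 6.36, 7.81, 7.94, 7.77 and 9.38 in the same 5 arrays, and from 5.94 in C3M1jaw to 7.93 in C2M3FT in the others. On chromosome 21, which holds SLC5A3, YBEY and ETS2, C3M1jaw lay at 0.34 in both blocks and C2M3FT at 0.37 in 1 of 2. Without the genes of the 8 chromosomes with such blocks, a setting added after the data were seen, 0 lists passed for metastatic against primary, while the means of the remaining members were 0.35 for YAP and TAZ and 0.20 for the mesenchymal list (adjusted p = 0.0741 in camera for both).

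**Figure D4:**
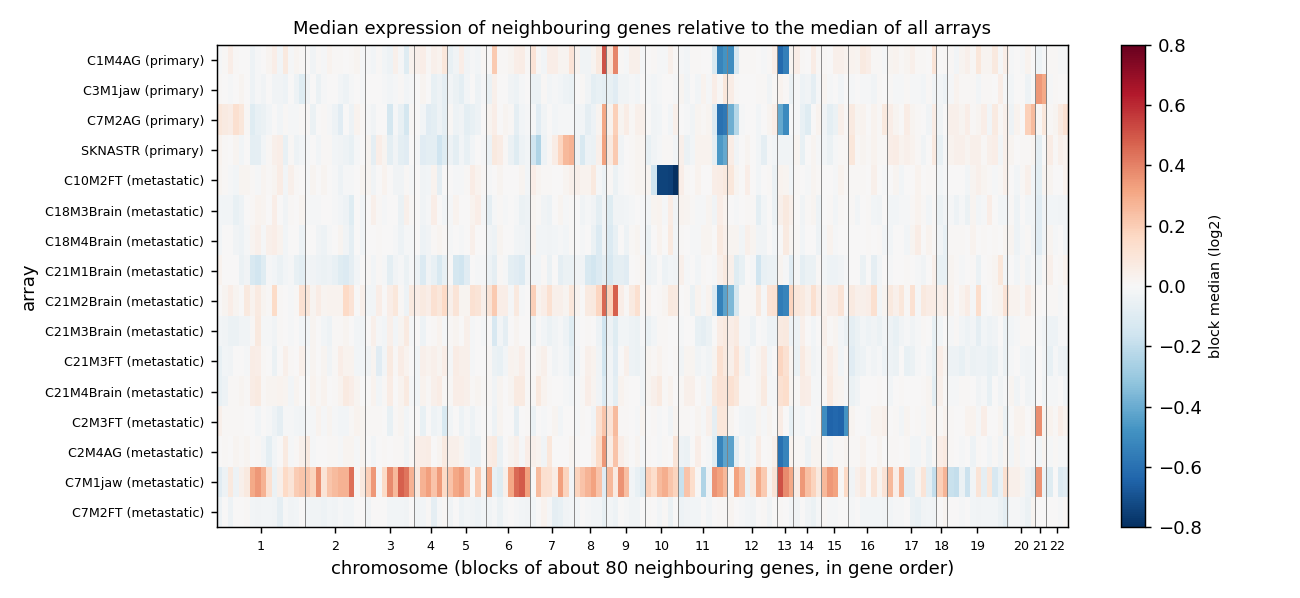
Median expression of 155 blocks of about 80 neighbouring genes (x axis, by chromosome) in each of 16 arrays (y axis), as log2 difference from the median of all arrays, with blue lower and red higher. Chromosome 10 in C10M2FT (-0.75) and chromosome 15 in C2M3FT (-0.59) stand out, as does the end of chromosome 11 in 5 arrays, while C7M1jaw has 30 blocks at least 0.3 from the median, spread over many chromosomes.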

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

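All tests of explanations in this part were chosen after the results were seen, apart from the counts over other splits of the samples for the design's comparisons and for the array weights.

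A value far from the other arrays of its group was found in 5 of 63 sets of values, where chance gives about 1 in 20. MYL12B read 12.52 and USP38 10.25 in the primary array C3M1jaw, above the nearest primary arrays at 12.39 and 10.02. ETS2 read 8.30 in C21M1Brain, below the nearest Brain array at 8.62. The fibroblast list had a mean of -0.40 in C21M2Brain and -1.31 in C2M3FT, against 0.28 and -0.02 in the nearest arrays of their suffix.

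Between Brain and FT, 4 lists differed: cell cycle by -0.33, MYC targets by -0.10, fibroblast markers by 0.51 and the interferon list by 0.17. Of 100 splits, the real one included, 67 gave as many lists, with 4 in the real split and 14 in the highest other, so chance cannot be excluded. For metastatic against primary, 74 of 100 splits, the real one included, gave as many lists, with 2 in the real split and 12 in the highest other. The list test assumed a correlation of 0.01 between genes, while the estimated value for the cell cycle list was 0.61 between Brain and FT. Whether that or a structure of the samples gives the many calls in other splits was not tested.

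No gene passed in metastatic against primary. With 0 genes in the real split every split gives as many (100 of 100), so this count decides nothing, and the highest other split gave 5. The same holds for Brain against FT (0 genes, 100 of 100, highest other 1) and FT against primary (0 genes, 35 of 35, highest other 3). In all counts here the real split is 1 of the splits. With array weights, 6 of 100 splits gave at least the 726 genes of the real split, and the highest other gave 2787. Brain against primary gave 1 gene, as many in 5 of 100 splits and 13 in the highest other, and with weights 1287, as many in 12 of 100 and 2771 in the highest other, so chance cannot be excluded for these 3 counts above 0.

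That C7M1jaw alone hides differences is argued against, because 0 genes passed without it, and 0 passed without C7M1jaw and C21M2Brain. Other values go the other way: array weights, lowest for these 2 arrays, gave 726 genes. Leaving out both raised Brain against primary from 1 to 290. Low weights fall on arrays far from their group's fitted mean, whether noisy or alike to the other group. C21M2Brain correlated at 0.913 on average with its own group and at 0.942 with the other. For C2M4AG, at a weight of 0.57, these were 0.943 and 0.972. For C2M4AG and C21M2Brain, noise alone is argued against, because both shared shifted blocks with the primary arrays C1M4AG and C7M2AG. In that order, these arrays lay at -0.48, -0.49, -0.51 and -0.58 on chromosome 11. On chromosome 13 they lay at -0.54, -0.55, -0.59 and -0.44. Of these blocks, the primary array SKNASTR had only those on chromosome 11, and C3M1jaw had none. Whether noise adds to the low weights was not tested. An exchange of labels between groups stays open. The most correlated array carried the other label for 6 arrays, 3 in each group. The shifted blocks group arrays without use of the labels, but they do not say which model an array came from. Exchanged labels and primary models that truly differ from each other therefore cannot be told apart. A biological difference between the metastatic and primary models stays open too.

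The array C7M1jaw stood apart in control signals outside the main measurement, with 5.78 for GAPDH and 7.37 for ACTB, above every primary array. A fault of hybridisation or scanning as the whole cause is argued against, because 18 probe sets for bacterial hybridisation controls lay on average only 0.20 from the other arrays. That was still the furthest of all arrays, with 0.12 in the next, so a small fault beside another cause stays open. Other technical explanations of these control values, RNA quality among them, were not tested and stay open, and no biological explanation was tested.

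Neighbouring genes were shifted together in single arrays. In 15 arrays, with C7M1jaw left out for its control values, 41 pairs of array and block were shifted by at least 0.3, in 8 arrays. Shuffled gene orders gave as many in 0 of 1000 draws, which argues against chance placement. RNA quality is argued against for C10M2FT and C2M3FT, as far as the controls measure it. Their ACTB differences of 0.18 and 0.17 lay between those of C7M2FT (0.15) and C18M3Brain (0.38), which had no shifted block. For the other arrays RNA quality stays open. The highest GAPDH control difference among the 8 arrays was 0.04, but leaving out C7M1jaw, which has 30 shifted blocks, fixed that outcome. C21M2Brain has a low 18S control (11.2). A change in chromosome copy number may account for the pattern: 85.9% of the genes of chromosome 15 in C2M3FT and 89.9% of those in the shifted part of chromosome 10 in C10M2FT lay below the median of all arrays. DNA was not analysed here, and these blocks were chosen for being shifted, so this stays a hypothesis.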

How the results depend on the processing

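Of the alternatives, leaving out C7M1jaw with C21M2Brain, the AG suffix as a covariate, the C number as a fixed block and the removal of 8 chromosomes were chosen after the data were seen. Genes called for metastatic against primary stayed at 0 except with array weights (726) and the C number as a fixed block (2), and for Brain against FT at 0 except with array weights (2). Brain against primary gave 1287 with array weights, 0 with the mean of all probe sets and 0 with a 2-fold minimum. It gave 290 without C7M1jaw and C21M2Brain, and 1 to 6 on leaving out each array. FT against primary gave 99 with array weights, 1 without those arrays and 0 to 2 on leaving out each array. In both, the highest count on leaving out an array came without C3M1jaw. Lists called for metastatic against primary were 0 with an estimated correlation, 1 to 5 on leaving out each array, 1 with the AG covariate (chemokines, cytokines and receptors, with a mean of -0.33, so neither of the lists called otherwise) and 0 without the 8 chromosomes, where fewer genes were tested. The YAP and TAZ mean was 0.18 with the AG covariate and 0.35 without the 8 chromosomes, and the mesenchymal mean 0.11 and 0.20. Lists called were 5 without C1M4AG, 4 without C21M2Brain, C2M3FT or C2M4AG, and 1 without C18M4Brain, C21M1Brain or C7M2AG. Lists called between Brain and FT were 0 with an estimated correlation and 2 to 6 on leaving out each array, with 2 without C18M4Brain or C2M3FT and 6 without C21M3FT. Elsewhere the cause was not tested.

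The direction turned for CADM1 without primary replicate 3 (0.12), without primary replicate 4 (0.16, the array with no C number), among AG and jaw arrays (0.29) and with the AG covariate (0.081), and it ran from -0.51 to 0.16 on leaving out each array. Among AG and jaw arrays it turned for SPHK1 (-0.35), YAP1 (-0.18) and GAP43 (0.036). Within C number 7, with no test, MYC gave 0.08. The mean of adrenergic neuroblastoma identity turned without primary replicate 1 (0.03), without metastatic replicate 9 (0.044) and with the AG covariate (0.02), and ran from -0.14 to 0.04 on leaving out each array. Of 78 named gene results, 72 kept their direction in every alternative with a test, and of 2416 alternative values 34 passed the threshold. Most of these genes were chosen for a small p in the same arrays. The alternatives share most arrays, so kept directions are no independent support. The C number as a random block had a consensus correlation of 0.002 for metastatic against primary and -0.015 in the 4-group fit, and changed no count. The similarity of arrays sharing a C number had p values from 0.0763 to 0.203, and the difference ran from 0.10 to 0.30, highest without C number 21. No paired analysis was possible because over 1 shared number is needed, and metastatic and primary arrays share only C number 7, Brain and FT arrays only C number 21. The C number as a fixed block can still be fitted, which leaves those comparisons to the arrays of these numbers. Brain and primary arrays share no number, so their comparison is only indirect in this fit. In it MYC turned to 0.081 and, for Brain against FT, IFITM3 to -0.03.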

Other observations

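The test of the AG suffix was chosen after the data were seen, and the genes named from the fit with array weights were chosen after their values were seen.

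With array weights, the genes called between metastatic and primary models included VIP, TAC1 and RD3. VIP, vasoactive intestinal peptide, differed by -4.39 (SE 0.90) and TAC1, which encodes substance P, by -4.19 (SE 0.84), while RD3 differed by 3.74 (SE 0.74) and VIPR1, a receptor for VIP, by 3.16 (SE 0.70). LGR5, a receptor of the Wnt pathway, differed by -3.15, the integrin ITGA9 by 3.10 and the adhesion molecule L1CAM by 2.19. VIP lay below the median of the array in 11 of 16 arrays and TAC1 in 12, so their differences are against values not shown to be above background, and their sizes are uncertain. TAC1, which also passed with the AG suffix, was above it only in the 3 AG arrays (10.61 in C1M4AG, 8.66 in C2M4AG and 7.19 in C7M2AG) and in SKNASTR (7.44), and VIP in these 4 and in C21M2Brain. ITGA9 was below it in all 4 primary arrays. Adjusted p values in limma lay between 0.0256 and 0.0351 with weights and at 0.762 for each without. The weights ran from 0.13 in C7M1jaw and 0.32 in C21M2Brain to 2.68 in C21M3FT. None of the genes named here followed the label in every array. RD3 read 5.12 in C21M2Brain and 6.85 in C2M4AG, both metastatic, and 9.77 in the primary array C3M1jaw. The other primary arrays read 6.1, 6.23 and 6.5, and the other metastatic arrays 9.39 or more. In C21M2Brain, C2M4AG and C3M1jaw in turn, VIPR1 read 9.20, 7.51 and 11.52, and L1CAM 8.40, 7.84 and 10.72. LGR5 read 12.03, 11.71 and 9.47 there. For VIPR1 the other primary arrays read at most 9.19 and the other metastatic arrays at least 9.64. As 6 of 100 splits called as many genes, these values are candidates to measure again.

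A hypothesis was that the 3 arrays with the suffix AG, 2 primary and 1 metastatic, share an expression difference. With the metastatic or primary label in the fit, 10 genes passed in limma, 3 higher and 7 lower. TAC1 was higher, with a mean of 8.82 in the AG arrays and 3.39 in the others, the latter below the array medians, so no size is given. PRRX2 was higher by 1.91 and NGEF by 1.53. SLC2A3, a glucose transporter, fell by 3.11 (SE 0.48), to a mean of 5.26, and BHMT2 fell by 2.78, to 6.29. Both means lay below the array medians, so these sizes are uncertain. As many genes were called in 6 of 100 splits into 3 and 13 arrays, the real one included, and the highest other split gave 1419, so chance cannot be excluded. The 3 arrays correlated with each other at 0.979 to 0.985. Shifted blocks lay in all 3 on chromosome 13 (-0.59 in C1M4AG, -0.54 in C2M4AG and -0.44 in C7M2AG), chromosome 12 (-0.50, -0.43 and -0.39) and chromosome 8 (0.51, 0.35 and 0.31), besides chromosome 11. The Brain array C21M2Brain had the same blocks, with -0.55 on chromosome 13, and the primary array SKNASTR those on chromosomes 8 and 11. Of the 7 lower genes 3 (42.9%) lie on chromosomes 11, 12 or 13, against 13% of the genes tested. All 3, SLC2A3, SPSB2 and LRRC23, lie on chromosome 12, and the hypothesis stays open.

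Within C number 7, where 2 metastatic arrays and 1 primary array share the number, HDAC9 read 8.17 and 8.76 against 5.48, and LPAR3 7.02 and 6.64 against 8.54. These are 2 of the larger differences. PTPRN read 6.54 and 7.36 against 7.54, and CAVIN2 5.87 and 6.79 against 6.71, so CAVIN2 was not lower in both. One of the metastatic arrays is C7M1jaw, and no test was made.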
